A study of Rattus norvegicus with 2 samples.

How the data were processed

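Dorsal skin of male WBN/Kob rats of 25 weeks was compared between wild-type rats (WT) and rats of the Ht line, a model of Olmsted syndrome with a Trpv3 gain-of-function mutation. Per the labels, skin was frozen at once, total RNA was extracted with TRIzol and cleaned on RNeasy columns, and Cy3-labelled cRNA was made with Agilent's low-input single-colour kit. RNA of 3 rats was pooled per genotype and each pool was hybridised to 1 array, so the design holds 1 sample per group, and leaving out a replicate, a block or a test of the genotype was not possible. A difference between the pools holds the genotype, the differences between the pooled animals and the error of 1 array each.

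Per the file headers, the arrays were of an Agilent rat design, scanned in 1 colour and read with Agilent Feature Extraction 11.5.1.1, a version that the submitters' processing notes also name. The deposited scanner files hold a spot intensity on a linear scale, which the software had background-subtracted and detrended and had not scaled between arrays. Per the file headers, both arrays lay on the same slide and were scanned together, so slide and scan do not separate the groups. Each array had 62976 spots, 58717 of them not controls, in 45598 probes, of which 1350 had 10 spots and 969 had 2. The median intensity was 88.6 for WT and 84.2 for Ht, 42185 and 41587 spots were well above background, 328 and 293 were marked as outliers and left out, and 0 were saturated. The authors' value table holds each spot's processed intensity times 1 constant per array, on a linear scale, with column medians of 492 for WT and 498 for Ht. The log2 factors were 0.14 for WT and 0.27 for Ht, with an SD over spots of at most 0.0002, and why they were chosen is not given in the sources used here. The table lists 41212 spots, each well above background on the Ht array, including 1017 of the 1019 spots above background in Ht only and 0 of the 1617 above background in WT only. It therefore served as an alternative.

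The value of a spot was log2 of its processed intensity minus the array's 75th percentile over spots other than controls, at an intensity of 1569 for WT and 1472 for Ht. Spots of a probe were averaged, a gene took its probe with the highest mean over both arrays, and the difference is Ht minus WT. The files give no gene symbols. Probes were named through the RefSeq accession in the files, without versions, in a table of the GRCr8 assembly, which named 21109 of 45598 probes (46.3%), and 16581 genes. No coordinates are given, because the array's design refers to another assembly. The 24489 other probes, among them all 6958 with Ensembl identifiers, were not named, so genes such as Flg, Krt10 and Krt6a were not analysed here. A gene was counted where any of its probes was well above background on at least 1 array, as 12882 were, 12250 of them on both arrays, 435 in WT only and 197 in Ht only. For 16 genes that status came from another probe than the value. Of 104 genes past 2-fold with several probes above background on both arrays, all probes of 94 had the same sign. For a gene above background on 1 array the text gives a lower bound of the fold, the bright value against the higher of the dim array's lowest signal well above background and the dim probe's own value. The words "at least" before such a fold refer to this bound under the main processing only. The bound does not allow for the error of repeated spots, so it is no statistical limit. It is no limit under other processing either, and normexp gave smaller differences for such genes.

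Genes were described by size, with a log2 difference of at least 1 called 2-fold. For a gene list the median difference was set against the medians of 10000 random lists of the same size matched on mean signal in 20 bins, and a list outside their central 95% was said to lie outside the random range. Counts and medians use the measured difference also where a gene was detected on 1 array. This describes the 2 arrays and is no test of the genotype. Lists of fewer than 4 genes above background were not scored. The lists, the rule for named genes and all alternatives but 1 were chosen before the data were examined. That rule took Trpv3 and the lipoxygenase list, the 10 highest and 10 lowest genes above background on both arrays with a proper symbol and probes of the same sign, the 5 largest bounds in each direction, up to 4 members past 2-fold per list or the largest 2 where none was, and housekeeping genes. A few genes that the rule takes are not reported here. Older symbols were read through the reference's synonyms.

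The spread of repeated spots of a probe gave an SD of the difference of 0.50 in the dimmest of 10 bins of mean signal, 0.16 in the next and 0.06 to 0.11 above it. This covers error within an array only, not labelling, pooling or animals. The 8 spike-in control probes had a median difference of -0.02 and ranged from -0.19 to 0.03. On simulated data over 12882 genes with 200 altered, 93% of genes altered by 1.5 on the log2 scale and 100% of those altered by 2.0 passed 2-fold, as did 0.371% of unaltered genes. Of lists of 20 genes with 10 raised, 100% lay outside the random range, as did 8% of unaltered lists. The simulation drew each unaltered gene independently with the same assumed spread at every brightness. These shares therefore follow from that choice and are no error rates of these arrays.

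Alternatives were scaling on the median, scaling on the 75th percentile of probes above background on both arrays, quantile normalization, cyclic loess, normexp background correction with an offset of 50, the authors' value table, the mean of all probes of a gene, a filter on both arrays, no filter, and leaving out saturated spots. Setting genes above background on 1 array to their bound was added after seeing the data. The files have no mean signal column, so normexp used the median signal of spots and background. Analyses used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 for quantile, loess and normexp.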

Results

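Gene expression was measured in the dorsal skin of male rats of the WBN/Kob strain (Wistar Bonn/Kobori) at 25 weeks of age. One array held RNA pooled from 3 wild-type rats (WT), and the other held RNA pooled from 3 rats of the line labelled Ht, a model of Olmsted syndrome. Olmsted syndrome is an inherited skin disorder with thickened skin and itch, and the Ht rats carry a gain-of-function mutation of Trpv3, a warmth-activated calcium-permeable channel of keratinocytes. The Ht skin came from areas without lesions, so the comparison asks how such skin differs from wild-type skin in its gene expression. The title of the series names metabolites of 15-lipoxygenases. The arrays do not measure metabolites, so only transcripts of the enzymes are described. Each array carried 58717 spots other than controls, of which 71.8% on the WT array and 70.8% on the Ht array were well above background. With 1 array per genotype no difference has a replicate check and no p-value is given. Differences are Ht minus WT on the log2 scale and are described by size, and the number of arrays limits their precision.

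Trpv3 itself (NM_001025757) had nearly equal signals in both pools. Its difference of -0.15 was smaller than the spot-to-spot error of 0.50 in the dimmest bin of mean signal, near whose upper edge the gene lay. It was about the size of the error of 0.16 in the next bin. A gain-of-function allele need not alter the level of the transcript. Both 15-lipoxygenase genes were lower in the Ht pool. Alox15, which oxygenates arachidonic and linoleic acid, was well above background in WT only and was at least 3.13-fold lower in Ht, and Alox15b was likewise detected in WT only and was at least 3.43-fold lower. Alox12, the platelet-type 12-lipoxygenase, was 2.37-fold lower, with a difference of -1.25. The remaining lipoxygenase genes differed by less than 2-fold. Alox12e, the epidermal-type 12-lipoxygenase, differed by -0.50, whereas Alox12b and Aloxe3, which act in sequence to build the epidermal water barrier, differed by 0.36 and 0.33. Alox5 and its activating protein Alox5ap both differed by -0.09. Of the 8 genes, 3 were at least 2-fold lower and 0 were at least 2-fold higher. The list median was -0.29, inside the range of -0.38 to 0.29 that held the central 95% of the medians of 10000 random lists matched on brightness (the random range). Among the alternatives it was -0.05 at the smallest, but it lay below the random range under normexp background correction. That correction also reduced the measured difference of Alox15 from -2.12 to -0.38, gave -0.41 for Alox15b and -0.52 for Alox12, and so left none of the 3 genes past 2-fold. Both 15-lipoxygenase genes were dim in WT, with scaled log2 signals of -6.03 for Alox15 and -5.90 for Alox15b against a lowest detected signal of -7.75. The arrays do not tell which cells of the skin samples the lipoxygenase signals came from. All 6 erythroid markers were lower in Ht too, with a median of -1.58, and whether blood cells carried part of these signals was not tested.

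**Figure D1:**
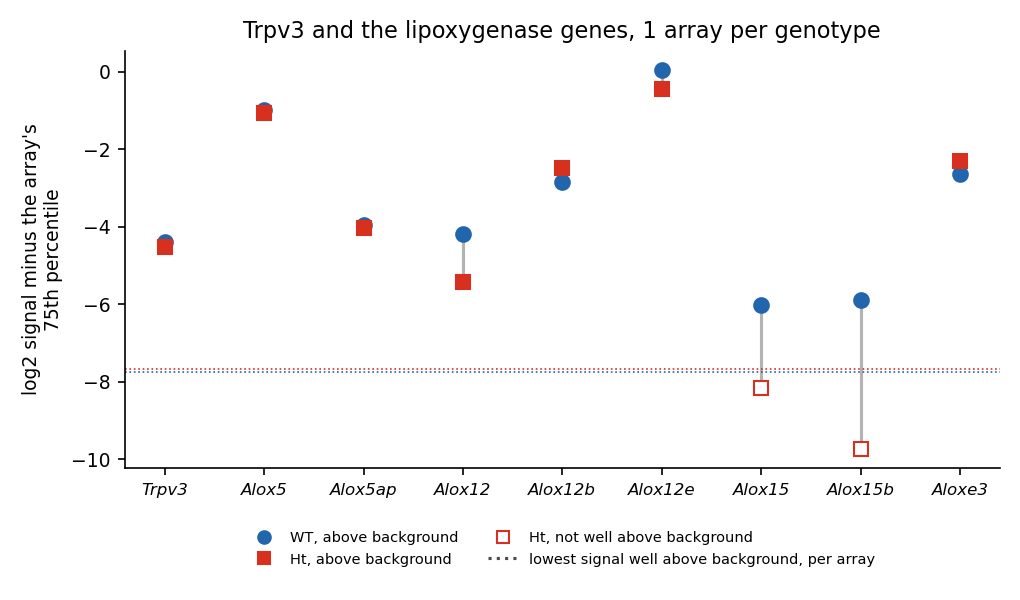
Scaled log2 signal (vertical axis, log2 signal minus the array's 75th percentile) of Trpv3 and the 8 lipoxygenase list genes on the WT array (circles) and the Ht array (squares), 1 array each. Open squares mark Alox15 and Alox15b, which were not well above background on the Ht array, and dotted lines mark the lowest signal well above background on each array, -7.75 for WT and -7.68 for Ht.

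Most named genes had similar levels in both pools. Among 12882 named genes well above background on at least 1 array, 457 (3.55%) were at least 2-fold higher in Ht and 677 (5.26%) were at least 2-fold lower, and 91.2% differed by less than 2-fold. Of the genes above background on both arrays, 349 were higher and 424 lower by at least 2-fold, and 17 were higher and 37 lower by at least 8-fold. These counts leave out probes without a gene name, which leaned the other way. Of 13971 such probes above background on at least 1 array, 976 were at least 2-fold higher and 868 lower. The housekeeping genes had a median difference of 0.10 and all 14 lay within 2-fold, among them Actb at -0.23, Gapdh at 0.29 and B2m at 0.09. The counts depended on how dim genes were treated, with 178 higher and 205 lower under normexp and 692 higher and 1215 lower with no filter. In the authors' value table, which lists only spots above background in Ht, the calls turned to 502 higher and 385 lower, so that 56.6% were higher against 40.3% here.

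Of the 10 lowest genes above background in both pools, leaving out those with only a placeholder symbol, 6 encoded keratin-associated proteins of hair. Krtap20-2l1 was 456-fold lower in Ht, a difference of -8.83 that was -7.02 under normexp, and Krtap4-7l2, Krtap19-5, Krtap2-1, Krtap14 and Krtap1-5 were between 51.4-fold and 29.2-fold lower. The others were Cts7, a cathepsin, at 73.8-fold lower, the secreted cysteine-rich protein gene Crisp3 at 57.5-fold lower, persephin (Pspn), a neurotrophic factor of the GDNF family, at 51.9-fold lower, and Cds2, an enzyme of phosphoinositide synthesis, at 28.1-fold lower. Cts7, Crisp3, Pspn and Cds2 were each measured by 1 named probe. The placeholder genes LOC102551201 and LOC102551168 were lower still, at -9.13 and -8.95. Among genes detected in WT only, the largest lower bounds were those of Pcdh12, at least 29.6-fold lower in Ht, the hair keratin Krt39, at least 15.4-fold lower, and the gastric lipase gene Lipf, at least 10.7-fold lower. Kcne5 and Kap followed with at least 9.45-fold and at least 8.60-fold. Normexp gave smaller differences than these, with -4.91 for Cts7, -3.80 for Crisp3, -4.59 for Pspn, -4.01 for Cds2, -2.07 for Pcdh12, -1.20 for Krt39 and -1.02 for Lipf, and Kcne5 at -0.96 and Kap at -0.86 were within 2-fold.

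Of the genes above background in both pools, placeholder symbols left out, Lao1, an L-amino acid oxidase that releases hydrogen peroxide, was the highest, at 94.1-fold higher in Ht, and Cxcl1, a neutrophil-attracting chemokine, was 42.8-fold higher. Lyg1, a lysozyme-like gene, the organic cation transporter Slc22a2 and the calprotectin subunit S100a9 were 15.9-fold, 15.9-fold and 15.8-fold higher. The transcription factor Fosb was 13.8-fold higher, the stefin Stfa3, a cysteine protease inhibitor, 12.4-fold, and the sodium iodide symporter Slc5a5 11.1-fold, followed by Serpinb10 at 10.2-fold and Aadacl2fm3 at 9.33-fold. Several of these folds rest on dim WT signals, and under normexp, which shrinks dim differences, Lao1 differed by 4.86 against 6.56, Cxcl1 by 2.77 against 5.42, Lyg1 by 2.79 against 3.99, Slc5a5 by 2.56 against 3.47, Slc22a2 by 1.92 against 3.99 and Fosb by 1.87 against 3.79. Among genes detected in Ht only, the largest lower bounds were those of the beta-defensins Defb5 and Defb4, at least 105-fold and at least 30.2-fold higher, the chemokine Cxcl2, at least 13.4-fold, Rnase3, at least 12.7-fold, and Paep, at least 12.5-fold higher. Normexp gave differences below these bounds, with 3.49 for Defb5, 2.04 for Defb4, 1.30 for Cxcl2, 1.13 for Rnase3 and 1.28 for Paep.

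**Figure D2:**
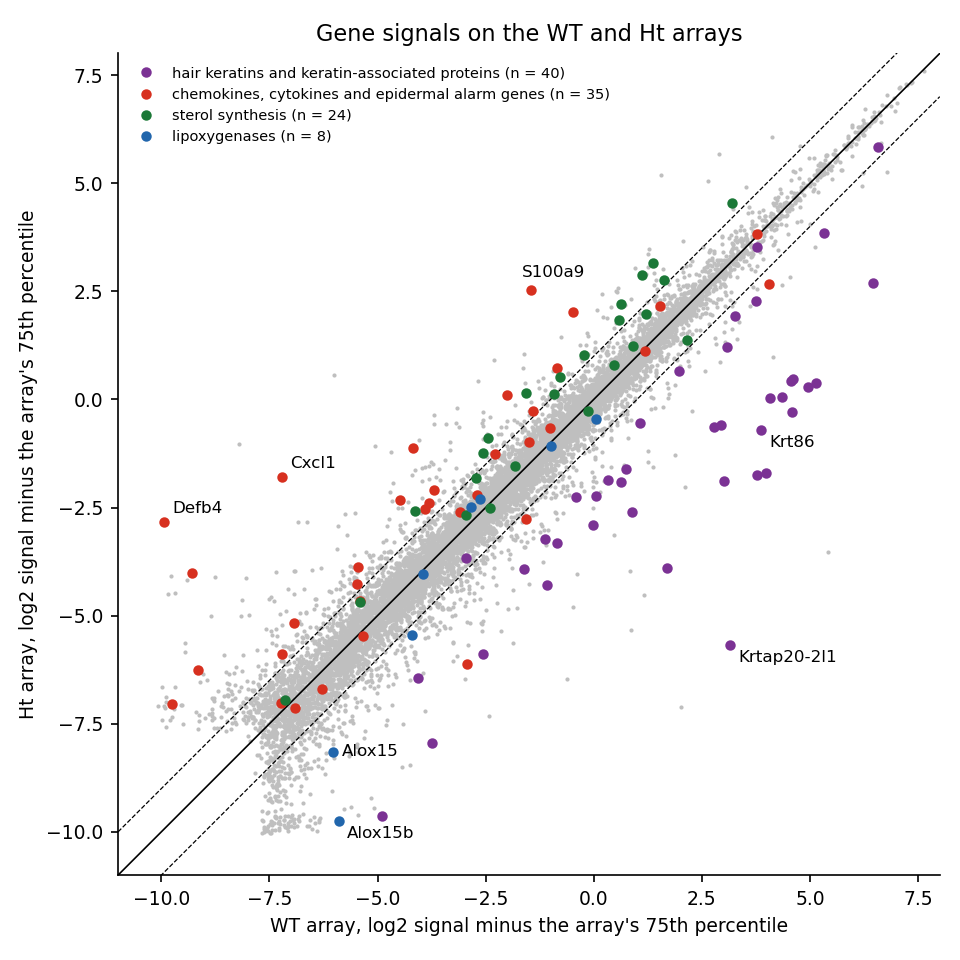
Scaled log2 signal of each named gene above background on at least 1 array, WT on the horizontal and Ht on the vertical axis, with the line of equality and dashed lines at 2-fold. The hair keratin and keratin-associated protein genes lie below the line, down to -8.83 for Krtap20-2l1, or -7.02 under normexp, whereas most chemokine, cytokine and epidermal alarm genes lie above it, with Cxcl1 at 5.42, or 2.77 under normexp.

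Hair structural genes had the lowest medians of the 45 scored lists. All 19 keratin-associated protein genes above background, which encode the matrix of the hair shaft, were at least 2-fold lower in Ht, with a median of -3.77. Of the 21 hair shaft and inner root sheath keratin genes, 18 were at least 2-fold lower and 0 higher, with a median of -2.47. Krt86 was 23.7-fold lower, Krt34 17.7-fold lower and Krt84, detected in WT only, at least 6.86-fold lower. Regulators of the hair follicle cycle had a median of -0.51, or -0.45 with genes detected on 1 array at their bound, and 8 of 34 were at least 2-fold lower. These included Fgf5, which ends hair growth, at 6.53-fold lower, Fgf18 at 3.92-fold, the desmosomal cadherin Dsg4 of the hair shaft at 3.68-fold and the hair transcription factor Foxn1 at 2.84-fold lower. Under normexp Fgf5 at -0.75, Foxn1 at -0.52 and Krt84 at -0.71 were within 2-fold. Each of the 3 medians lay below all 10000 random lists, and each list stayed outside the random range in every alternative run on it, although plain rescaling could not have altered this. Proliferation genes, which growing follicles express, had a median of 0.04 inside the random range, and 1 of 27, the mitotic kinase Aurka, was at least 2-fold higher, at 2.34-fold, but its difference was 0.74 with the mean of its probes. Keratin genes of a family are close in sequence, so that a probe can read RNA of several members and the members are not independent counts.

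The lipid synthesis lists had medians above the random range. Sterol synthesis had 13 of 24 genes at least 2-fold higher and 0 lower, with a median of 1.10. Ebp, Cyp51 and Idi1 were 3.44-fold, 3.41-fold and 2.97-fold higher. Fatty acid synthesis, elongation and desaturation had a median of 0.71, with 3 of 23 genes at least 2-fold higher and 1 lower. Elovl4, which makes the very long acyl chains of barrier ceramides, was 4.82-fold higher, Elovl3 4.03-fold and Acacb 3.10-fold higher, and Fads3 was 2.08-fold lower. Genes of epidermal ceramide and barrier lipid processing had a median of 0.38, with 4 of 23 higher, among them Lipn at 3.02-fold and Sptlc3 at 2.97-fold, and 1 lower, Fa2h at 2.60-fold. The 3 medians lay above all random lists. Sebaceous gland markers had a median of 0.93, and 0.59 at the lowest among the alternatives. Of the 14 genes, 7 were at least 2-fold higher, including Cidea at 3.87-fold, Dgat2l6 at 3.46-fold and the wax synthase Awat1 at 3.25-fold. Elovl3 and Fa2h belong to that marker list as well. Under normexp Acacb at 0.78, Fads3 at -0.90, Sptlc3 at 0.78, Fa2h at -0.57 and Dgat2l6 at 0.93 were within 2-fold.

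The other enzymes of eicosanoid metabolism went both ways. Cytochrome P450 and epoxide hydrolase genes had a median of 0.29 above the random range, with Cyp2b12 6.23-fold, Cyp2b15 4.29-fold and Cyp2j10 3.52-fold higher and the epoxide hydrolase Ephx1 3.43-fold lower. The cyclooxygenase and prostanoid list had a median of -0.03, inside the random range, with 2 of 19 genes at least 2-fold higher and 1 lower. Akr1c3, listed under its older symbol Akr1c18, was 5.03-fold higher, Ptgs2, the inducible cyclooxygenase, was detected in Ht only and was at least 1.77-fold higher, and the prostacyclin synthase Ptgis was 2.09-fold lower. Under normexp Cyp2j10 at 0.74, Ptgs2 at 0.23 and Ptgis at -0.40 were within 2-fold. Leukotriene synthesis and receptor genes had a median of -0.04, with Ggt1 2.86-fold lower and the other 10 within 2-fold. Phospholipases A2, which release arachidonic acid, had a median of -0.26 below the random range, although the secreted enzyme Pla2g2a was 5.05-fold higher and the other 12 were within 2-fold. The call on phospholipases A2 was lost under quantile normalization, normexp and no filter.

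The epidermal alarm and chemokine lists had medians above the random range. Of 17 stress keratin and alarm genes, 11 were at least 2-fold higher and 3 lower, with a median of 1.41. Besides Defb4 and S100a9, Il24, detected in Ht only, was at least 2.83-fold higher, whereas S100a7a was 9.11-fold lower. Innate and neutrophil-attracting cytokines and chemokines had a median of 0.97, or 0.73 with genes detected on 1 array at their bound, and 9 of 18 were at least 2-fold higher and 0 lower. Besides Cxcl1 and Cxcl2, Ccl20, which attracts cells that bear Ccr6, was 8.27-fold higher, and Il17a, detected in Ht only, was at least 1.64-fold higher. Both medians lay above all random lists, and under normexp they were 0.80 for the alarm genes and 0.41 for the chemokines, still above the random range. Neutrophil markers had a median of 1.30, which is the value of Cxcr2 alone, and it was as low as 0.17 with no filter. Of the 5 markers, S100a8 at 5.66-fold higher and S100a9 belong to the alarm list as well, and the other 3 had a median of -0.056, with 2 of them within 2-fold. Macrophage markers had a median of 0.11 inside the random range, with Lyz2 1.71-fold and Cd163 1.58-fold higher. T cell markers had a median of 0.30 above the range, with Cd8a at least 2.40-fold and Cd5 at least 2.01-fold higher, each detected in Ht only, and that call was lost with genes detected on both arrays only and in the authors' table. Under normexp Il24, Il17a, Cxcr2, Cd8a and Cd5 were within 2-fold, between 0.18 for Cd5 and 0.44 for Cxcr2, S100a7a differed by -1.56 and Ccl20 by 2.20.

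Without Il31 and Tslp, which had no named probe, the 14 of 25 type 2 and itch genes above background did not stand apart as a list. Their median was 0.04, with the chemokine Ccl17 5.94-fold higher and 2 of 14 genes lower, namely Postn at 2.72-fold and Il13, detected in WT only, at least 1.29-fold. Interferon response genes had a median of -0.01, with 25 of 26 within 2-fold and Oasl, detected in WT only, at least 1.97-fold lower. MHC class II genes had a median of 0.37 above the random range, although RT1-DMb was 2.59-fold lower. Mast cell markers had a median of -0.50 below the range, and -0.29 at the smallest among the alternatives, with 4 of 12 at least 2-fold lower. Of these, Mcpt1 was 2.58-fold, Tpsab1 2.55-fold, Cpa3 2.13-fold and Cma1 2.05-fold lower. Only 3 of 8 eosinophil markers were above background, too few to score, and they went both ways, with Rnase3 as given above, Siglec5 2.11-fold higher and Prg2 11.2-fold lower. The 4 B cell and plasma cell markers had a median of -0.04, with Cd79b detected in WT only, and the 5 Langerhans and dendritic cell markers had a median of 0.15, with Ccr7, detected in Ht only, at least 2.06-fold higher. Both were inside the random range. Under normexp Il13 at -0.14, Oasl at -0.09, Cpa3 at -0.96, Cma1 at -0.99, Siglec5 at 0.32 and Ccr7 at 0.28 were within 2-fold, and Ccl17 differed by 1.40, Prg2 by -1.73 and Rnase3 by 1.13.

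Among genes of the epidermis itself, cornified envelope genes went both ways, with a median of -0.06 inside the random range, 2 of 18 at least 2-fold higher and 4 lower. Several list members had no named probe, among them Flg, Krt10, Cdsn and the loricrin gene. The median therefore does not describe terminal differentiation as a whole. Casp14, a protease of cornification, was 4.50-fold and the suprabasal keratin Krt1 3.87-fold higher, while Krt77 was 12.7-fold and Sprr3 2.75-fold lower. Epidermal proteases and inhibitors had a median of 0.48 above all random lists, with 6 of 18 higher and 1 lower. Serpinb12 was 6.38-fold, Klk9 5.44-fold and Klk8 3.03-fold higher, and Klk1 was 4.69-fold lower. Basal keratinocyte genes had a median of 0.33 above the range with all 10 within 2-fold, led by Krt14 at 1.57-fold and Tp63 at 1.40-fold higher. The list of EGF receptor ligands had a median of -0.004, with Ereg 4.95-fold and Epgn 2.12-fold higher and the other 13 genes within 2-fold. TRP channel genes had a median of -0.15 inside the range, with the heat and capsaicin receptor Trpv1 3.61-fold lower and Trpv6, a calcium channel, 2.25-fold lower. Trpc4 was past 2-fold at 1.19, but its brightest probe was not well above background in WT, at -8.78 against a lowest detected signal of -7.75. The probes of Trpc4 disagreed, with -0.88 for their mean. Calcium signalling genes had a median of -0.01, with S100a3, a hair shaft protein, 3.27-fold and Plcd1 2.01-fold lower. Under normexp Trpv1 at -0.40, Trpv6 at -0.82, Sprr3 at -0.19 and Epgn at 0.88 were within 2-fold, Krt77 differed by -2.89 and Klk1 by -1.19, and Plcd1 was -0.70 with the mean of its probes.

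The dermal matrix, fibroblast and nerve lists had medians below the random range, although most of their genes were within 2-fold. The matrix list had a median of -0.58 below all random lists, with 6 of 24 genes at least 2-fold lower, among them Postn and Col14a1, the latter at 2.57-fold, and 2 higher, the collagenase Mmp13 at 7.78-fold and the stromelysin Mmp3 at 4.14-fold. Fibroblast markers, which share 5 genes with that list, had a median of -0.32, with Fap 2.16-fold and Lum 2.10-fold lower. Nerve growth factors, neuropeptides and guidance genes had a median of -0.62 below all random lists, and -0.25 at the smallest among the alternatives. Of the 21 genes, 5 were at least 2-fold lower and 2 higher. Penk was 3.35-fold, Calcb 3.02-fold and Sema3a 2.63-fold lower, and the natriuretic peptide gene Nppb, linked to itch transmission, was 8.76-fold higher. Under normexp Penk at -0.85, Calcb at -0.70, Sema3a at -0.51 and Lum at -0.99 were within 2-fold, and Mmp13 differed by 1.10. Schwann cell and nerve markers had a median of -0.62, and that call was lost with no filter on dim genes. Probes of the myelin gene Mbp disagreed, with -1.06 for the brightest and -0.39 for their mean.

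Stress and metabolic lists differed little between the pools. Immediate early and heat shock genes had a median of 0.19 above the random range, with Fosb, Fos at 8.63-fold and Dusp1 at 2.25-fold higher and Dusp2 2.57-fold lower, and the other 24 genes within 2-fold. Under normexp Dusp1 at 0.70 and Dusp2 at -0.95 were within 2-fold, and Fosb differed by 1.87. Oxidative stress response genes had a median of 0.12 inside the range, though above it with no filter on dim genes, with the cystine transporter Slc7a11 3.88-fold lower as the 1 gene past 2-fold. Oxidative phosphorylation genes had a median of 0.12 above the range, and all 80 were within 2-fold, with Ndufa10 1.53-fold and Ndufb9 1.31-fold higher. The 99 genes taken by the ribosomal protein list, which also holds S6 kinase genes such as Rps6ka2 at 0.69, had a median of -0.01 inside the range, though below it under quantile normalization, and Rps4y2 differed by -0.64.

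Markers of other tissues differed between the pools as well. All 6 erythroid markers were lower in Ht, with a median of -1.58, including Ahsp at 6.83-fold, Hba-a2 at 3.26-fold, Hbb at 2.99-fold and Hbb-b1 at 2.97-fold. Smooth muscle and pericyte markers had a median of -0.31 below the range, with Cnn1 3.56-fold lower. Skeletal muscle markers had a median of 0.18 above the range, with Myh7 2.98-fold and Mb 2.60-fold higher. Endothelial markers had a median of -0.22 below the range, a call lost under quantile normalization, normexp and the mean of all probes. The probes of Flt1, one of these markers, disagreed, with 1.11 for the brightest, 0.45 for their mean and 0.39 under normexp. Adipocyte markers had a median of -0.31 below the range, with Pck1 3.30-fold, Lep 2.53-fold and Aqp7 2.18-fold lower and Cidea, which the sebaceous list shares, higher, but the median was 0.04 in the authors' table. The 5 melanocyte markers had a median of 0.31 inside the range, with Tyrp1, detected in Ht only, at least 2.14-fold higher. Under normexp Cnn1 at -0.30, Pck1 at -0.94, Aqp7 at -0.72 and Tyrp1 at 0.30 were within 2-fold, Ahsp differed by -1.64, and Lep was -0.70 with the mean of its probes.

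**Figure D3:**
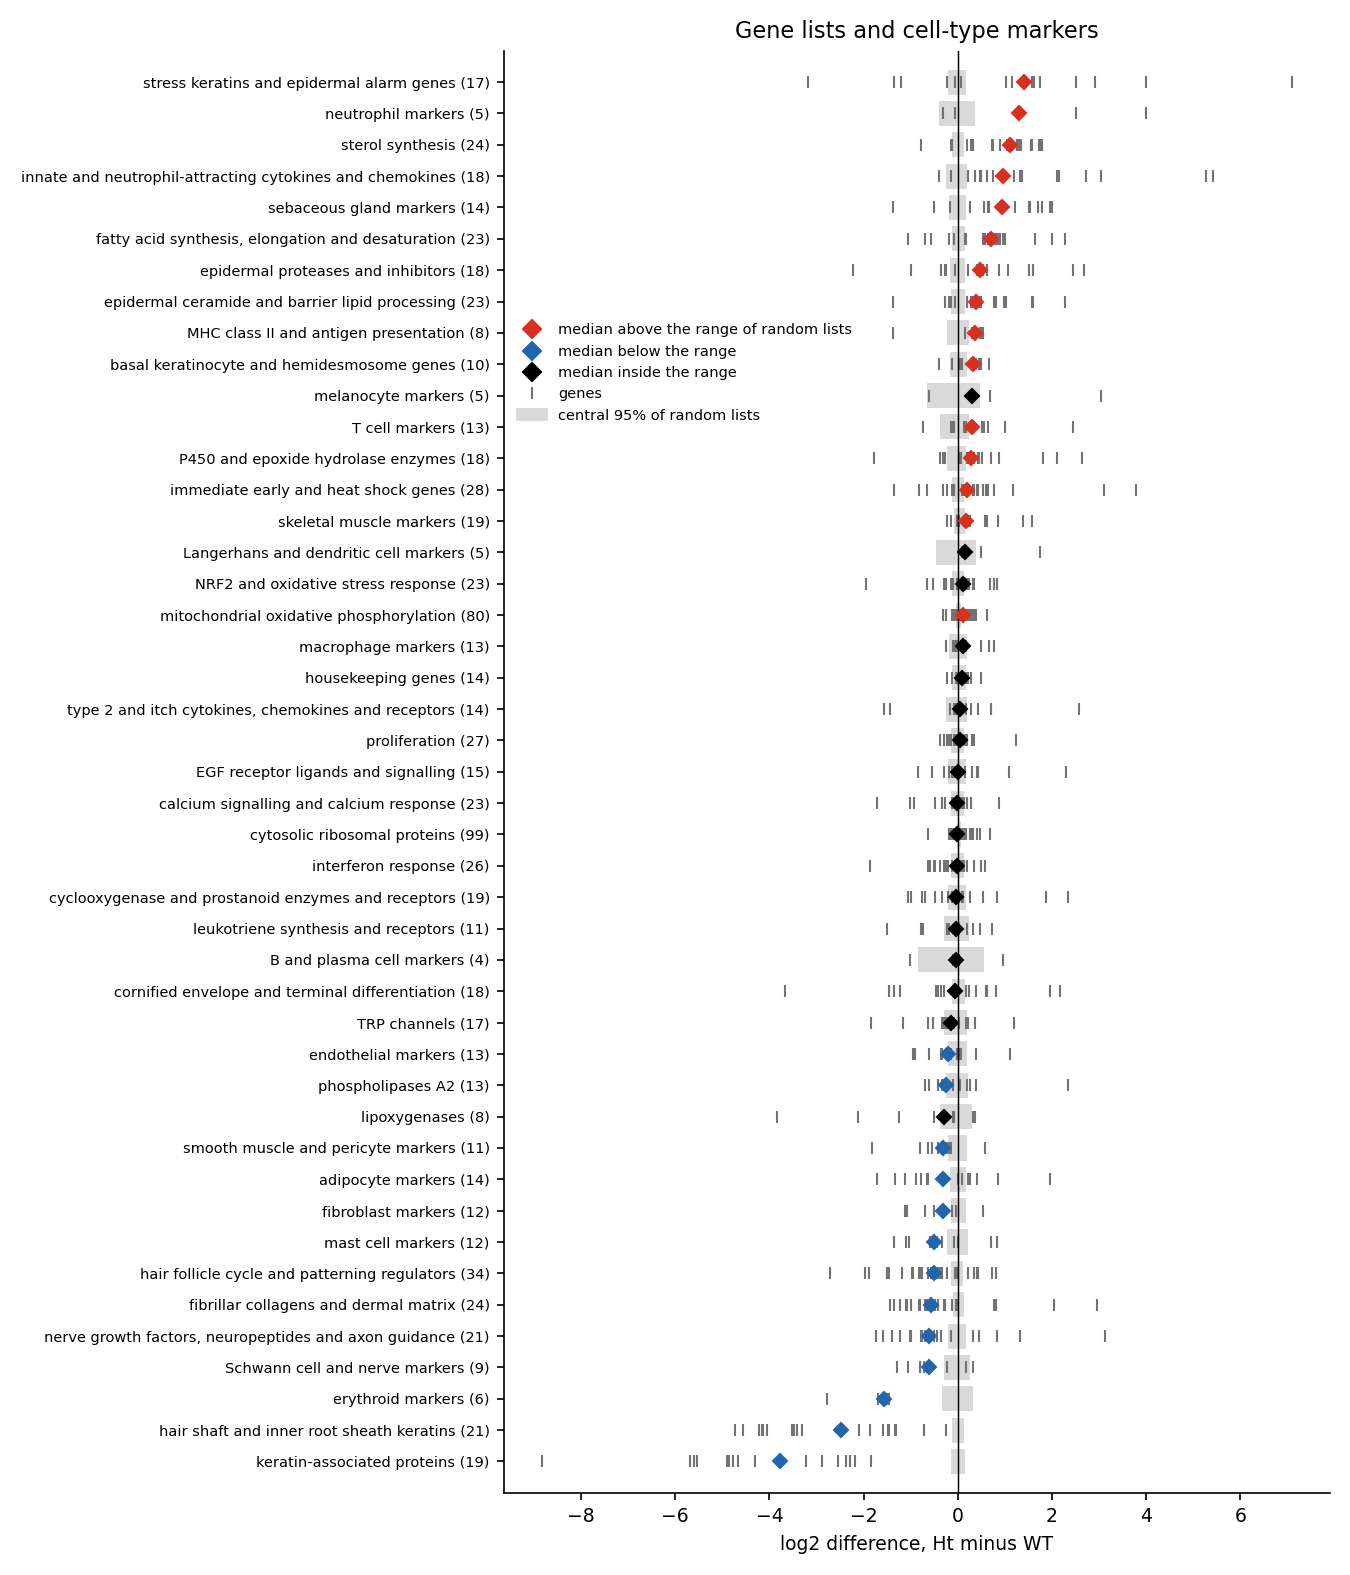
Log2 difference (horizontal axis, Ht minus WT) of the 45 scored gene and marker lists, with genes above background in parentheses, ticks for genes, diamonds for list medians and grey bars for the central 95% of medians of 10000 random lists. The medians run from -3.77 for the keratin-associated proteins to 1.41 for the stress keratins and alarm genes, and 15 lie above their bar and 13 below it.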

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

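The tests of brightness, growing follicles, sebaceous share, blood, handling and neutrophils in this part were chosen after the result was seen, whereas the gene lists they draw on were planned. Probes without a gene name here took no part in the comparisons, and they differed between the pools too. Of 13971 such probes above background on at least 1 array, 976 were at least 2-fold higher in Ht and 868 at least 2-fold lower, and 675 were well above background on the Ht array only and 942 on the WT array only. More of them were thus higher than lower, whereas of the 12882 named genes 457 were higher and 677 lower.

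Hair keratin and keratin-associated protein genes were lower in Ht, with a median of -3.27 over the 40 genes of both lists. A trend of the difference with brightness is argued against, since the medians of random lists of the same brightness had a central 95% of -0.095 to 0.097, and 0 of the 40 genes were above zero. Probes that read RNA of near-identical keratins were not tested, so how many of the keratin genes differed on their own stays open. Fewer growing hair follicles in the Ht pool is a candidate explanation that cannot be told apart from a difference within follicles, because proliferation genes, with a median of 0.037 inside the random range, are also expressed in the epidermis. The mutation of the Ht rats, and a chance difference in hair cycle stage between the pools of 3 rats, both stay open and were not tested.

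The sterol synthesis and sebaceous gland lists had medians above the random range. A larger share of sebaceous gland in the Ht pool would raise the 11 sebaceous markers that are in no lipid synthesis list. Their median was 1.21, above the random range of -0.23 to 0.22. These markers are part of the list that prompted the question and include lipid enzymes such as Awat1 and Dgat2l6. They therefore cannot tell a larger share of gland from higher lipid synthesis. These markers did not move alike, since their quartiles were 0.40 and 1.61, Mogat1 differed by -0.50 and Dgat2 by -0.16, so a difference within the gland stays open beside its share. The mutation itself stays open and was not tested.

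The chemokine and epidermal alarm lists had medians above the random range, and Fos and Fosb were higher in Ht. More blood in the Ht skin is argued against, since the erythroid markers had a median of -1.58, with all 6 lower in Ht. Slower handling of the Ht skin before freezing could raise immediate early genes besides Fos and Fosb. The 21 others had a median of 0.20 and an upper quartile of 0.44, far below Fos and Fosb, but 15 of them were above zero. Handling that raised all these genes alike is therefore argued against. Handling that raised Fos and Fosb more than the others is not excluded. Neutrophils in the Ht skin cannot be told apart from keratinocyte expression, because only 3 neutrophil markers outside the alarm list were above background, with a median of -0.056, Cxcr2 at 1.30, Ncf1 at -0.06 and Fpr1 at -0.31. The mutation, and inflammation that differed between the pooled animals for another reason, stay open and were not tested.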

How the results depend on the processing

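No paired analysis was possible because each genotype has 1 array. Over the alternatives, 23 of the 28 lists outside the random range stayed outside it on the same side in every alternative run on them, and the exceptions were phospholipases A2 and the T cell, endothelial, adipocyte and Schwann cell markers. Plain rescaling shifts all genes alike and could not have altered these calls, so it is no check on them. Normexp with its offset of 50 shrinks differences of dim spots by construction. It gave 178 genes higher and 205 lower, Alox15 at -0.38, Cd79b turned to 0.042, the lipoxygenase list at -0.22, now outside the random range, and phospholipases A2 at -0.062, now inside it. Phospholipases A2 also lay inside it at -0.23 under quantile normalization and at -0.18 with no filter, and the cause was not tested. With no filter 692 genes were higher and 1215 lower, since dim genes enter, and with genes above background on both arrays 349 were higher and 424 lower. Besides the lipoxygenases, of the lists inside the random range the ribosomal list left it under quantile normalization and the oxidative stress list with no filter, at 0.17. The authors' value table holds 0 of the spots detected in WT only and 40195 of the 40568 above background on both arrays, and gave 385 genes lower against 677, 384 of them among those 677, and 502 higher. It holds no value for Adipoq, and the adipocyte median turned to 0.040. The mean of all probes turned Trpc4 to -0.88, since its probes disagree. Leaving out saturated spots removed nothing, as 0 were saturated. The other scalings gave 449 to 492 genes higher and 639 to 702 lower. Setting genes detected on 1 array to their bound, chosen after seeing the data, gave 405 genes higher in Ht and 503 genes lower in Ht. Trpv3 kept a difference between -0.17 and -0.06. Signal over background limits the dimmest genes, where repeated spots gave an SD of the difference of 0.50.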

Other observations

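The gene families in this part were chosen after their values were seen, and no explanation of them was tested. Whether probes of related members read the same RNA was not tested either, so the members may not be independent counts. All 5 stefin genes above background, which encode inhibitors of cysteine proteases, were at least 2-fold higher in Ht, with a median of 2.57. Csta and Stfa3 differed by 2.77 and 3.63 and were among the bright genes of the Ht array, with scaled log2 signals of 5.67 and 5.19. Major urinary and odorant-binding protein genes, which encode small carriers of lipids and scents, had a median of 2.05, with 6 of 8 at least 2-fold higher, such as Obp3 at 2.20 and Mup4l3 at 2.26. Peptidylarginine deiminases, which convert arginine to citrulline in hair and cornifying cells, went both ways. Padi1 differed by -1.96, Padi3 by -1.46 and Padi4 by -1.26, whereas Padi2 was 3.99-fold higher. Members of the Serpinb family had a median of 0.25, with 3 of 12 at least 2-fold higher, among them Serpinb2 at 1.96. Whey acidic protein genes had a median of -0.37, with 2 of 9 higher and 3 lower.

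Of 33 RT1 genes, which encode the major histocompatibility complex of the rat, 31 were within 2-fold and the median was 0.09. RT1-CE4 stood far from the rest at -4.14, with scaled log2 signals of 2.11 in WT and -2.03 in Ht, and RT1-DMb differed by -1.37. Both were measured by 1 probe each.

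The authors' value table leaves out genes of the enzymes whose metabolites the series title names. Because that table lists only spots above background in Ht, the genes it lacks lean lower in Ht by construction. Of 499 genes above background on at least 1 array that the table does not hold, 254 were at least 2-fold lower in Ht and 0 at least 2-fold higher. Alox15 and Alox15b are among them, as are 3 of the 21 hair keratin genes, so a reader of that table sees 6 of the 8 lipoxygenase list genes.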
